A study of Mus musculus with 9 samples.

How the data were processed

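Single-cell RNA was measured in 9 libraries of lung tumours from a genetically engineered mouse model of small cell lung cancer. The genotype label is RPP, the field's short name for mice whose lung tumours lose Rb1, Trp53 and Rbl2. The labels do not spell it out, nor LSN, which was read as an Aurora A kinase inhibitor. Mice received vehicle (replicates 14 and 24), PD-L1 blockade (09 and 25), LSN (13 and 26), or both (12, 18 and 27; called LSN+PD-L1 or the combination here). Libraries are named by group and replicate, so Vehicle 14 is replicate 14 of the vehicle group. Each number was taken as 1 animal, which the labels do not state.

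Per the labels, tumours were minced and digested with enzymes, and 10x Genomics 5' libraries were sequenced. The deposited matrices held raw UMI counts (molecules counted per gene and barcode, no normalization) for all barcodes, empty droplets included. The submitters' notes name Cell Ranger 6.0.2 and mm10 for alignment and counting, whereas the matrix headers name Cell Ranger 4. Each matrix held 32287 features, 2 of them added sequences (EGFP and Cas9). LSN 13 held 32285 and lacked those 2, which therefore stayed out of the tests. Gene coordinates are those of GENCODE vM21 (mm10), in which 32158 of the 32285 gene identifiers were found. Libraries held 20955478 to 40261757 UMIs.

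Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, 28535 in all. Scrublet (scanpy 1.11.5) marked doublets. Its automatic threshold marked under 0.5% of the cells in every library except PD-L1 09, and in those 8 libraries cells scored above the quantile set by 0.8% per 1000 cells were marked, 1.37% to 4.41% of them, each below its expected rate. The 752 marked cells stayed out, which left 27783 cells, 1226 to 5441 per library. Median UMIs per cell ran from 2548 in LSN+PD-L1 27 to 14218.5 in PD-L1 09, and median genes from 1160 to 4597. Counts were log-normalised, and 2000 variable genes and 30 principal components went into Leiden clustering (leidenalg 0.10.2, resolution 1) without batch integration. The 28 clusters were named from marker lists of 20 classes, and 10 classes were found. The rules that turn marker levels into names were adjusted after the cluster tables, though not any group comparison, had been seen. Hemoglobin genes no longer counted against a name, and the choice within a lineage went by the 10 leading markers. Under the first form of the rule a tumour cluster rich in hemoglobin RNA, mostly from Vehicle 24, stayed unnamed. Results without that cluster are given as an alternative. Cells of 3 clusters (219 cells, 202 of them from LSN+PD-L1 27) met no naming rule and entered the shares as unnamed.

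Counts of each class were summed per library, since cells of 1 animal are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr and a mean per group. The LSN effect is the mean of LSN minus vehicle and combination minus PD-L1. The PD-L1 effect is the mean of PD-L1 minus vehicle and combination minus LSN, and the interaction is the difference between those PD-L1 differences. In tumour cells 5 comparisons of single groups were also tested. Benjamini-Hochberg adjusted p below 0.05 was the threshold in each comparison. A class planned for a test was tested where each library held at least 20 of its cells. Alveolar macrophages were not planned for one. Group levels are means of library CPM (a gene's counts scaled to the class's sum, as in edgeR) with SD, and fold changes are fitted values with SE. Fitted folds of genes with few UMIs depend on the prior count of the fit. DESeq2 1.42.0 was run beside edgeR. All tests were two-sided.

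Gene lists were S phase, G2 and M phase, mitosis, type I interferon response, interferon gamma response, MHC class I antigen presentation, MHC class II, nucleic acid sensing, neuroendocrine, non-neuroendocrine, apoptosis, dissociation and heat stress, hypoxia and glycolysis, T cell cytotoxicity, T cell exhaustion, naive and memory T cell, regulatory T cell, inflammatory macrophage and tissue repair macrophage. All 19 were tested in tumour cells and 9 each in T cells and macrophages. In the hypoxia and glycolysis list 1 symbol matched 2 gene identifiers, and both were tested. The lists overlap: Aurka, for instance, stands in both the G2 and M phase and the mitosis list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. camera compares a list with all other genes. The p of camera with a correlation estimated from the libraries is given beside each call, without adjustment, and fry was run too. Counts adjusted over the list alone are those of members with a Benjamini-Hochberg adjusted p below 0.05 among that list's genes, and a called list with no such count in the text had 0. With an estimated correlation, no list called in the text kept an adjusted p below 0.05. Its lowest was 0.0948, for tissue repair macrophage genes in the LSN effect in tumour cells, which passed in fry (adjusted p = 0.0231), as did T cell cytotoxicity genes in the combination versus vehicle (0.0444).

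The mitotic gene share is the percent of all tumour-cell UMIs of a library on the mitosis list, and interferon and MHC class I shares were taken the same way. Mitotic-high cells are those, among tumour cells of at least 2000 UMIs, with at least 5 UMIs of the mitosis list after each cell had been thinned at random to 2000 UMIs. These shares, the share of each class among a library's cells and the share of T cells with a Cd8a or Cd8b1 UMI were compared by exact permutation of the 9 libraries, treated against not treated. The 126 splits of 5 against 4 allow a smallest p of 0.0159. Class shares were adjusted over 20 tests. Wilson 95% intervals of shares of cells cover counting error only.

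Genes are named by a fixed rule. In each tumour-cell comparison these are the 10 highest and 10 lowest fold changes among genes past the threshold with a mean log2 CPM of at least 4 and no overlap between arms, up to 4 passing members per list, and 18 genes named whatever their p, 2 of which are not reported here. Where fewer than 20 genes passed, the 10 of smallest p are given as values. Other classes take 5 and 5. Predicted genes, ribosomal and mitochondrial genes and antibody or T cell receptor segments are not named among the strongest changes. No list member passed in tumour or T cells, so the examples given for a list are members of smallest p, a choice made after the values were seen. The 4 groups, comparisons, tests, thresholds, lists, markers and naming rule of genes, and the other settings to be tried, were set before the data were examined.

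The labels give neither batch nor sex. The matrices list between 349882 and 624922 barcodes each. Vehicle 24, PD-L1 25, LSN 26 and LSN+PD-L1 27 have longer lists (593135 to 624922) than the other 5 (349882 to 462616), and these sets of 4 and 5 libraries were treated as possible batches. Sex was read from tumour-cell sums. Xist stood at 495 to 1027 CPM in PD-L1 09, PD-L1 25, LSN 26, LSN+PD-L1 18 and LSN+PD-L1 27, taken as female. In Vehicle 14, Vehicle 24, LSN 13 and LSN+PD-L1 12, taken as male, Xist was at most 0.176 CPM and Y-chromosome genes reached 64.2 to 172 CPM. Both vehicle mice were thus male and both PD-L1 mice female.

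Alternatives covered the test (DESeq2), size factors, the filter on low counts, the groups in the fit, an additive model, the cell filter (1000 genes and 10% mitochondrial UMIs), doublets kept, Leiden resolution 2, other minimums for mitotic-high and CD8 cells, and each library left out. Added after the data had been seen were sex and barcode set as terms or subsets, and sets of cells or libraries that stood apart. Free RNA was estimated from barcodes of up to 100 UMIs. The tests were also run on simulated data, in which 200 genes and 1 list of 30 genes had been changed. EGFP and Cas9 counts stayed outside the comparisons.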

Results

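Small cell lung tumours in mice were profiled cell by cell after treatment with LSN, read here as an Aurora A kinase inhibitor, with an antibody block of the checkpoint ligand PD-L1, with both, or with vehicle. The layout asks what Aurora A inhibition does to the cell cycle and interferon genes of tumour cells, and whether it changes what PD-L1 blockade does to tumour and immune cells. LSN-treated libraries (LSN and LSN+PD-L1, n = 5) were compared with the others (n = 4), and PD-L1-treated libraries (PD-L1 and LSN+PD-L1, n = 5) with the others (n = 4).

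Neuroendocrine tumour cells were the most frequent class, with 15266 of 27783 cells, and had 314 cells in LSN+PD-L1 27 to 3470 in Vehicle 24. Besides them, 2961 macrophages and monocytes, 2731 B cells, 2641 T cells, 1328 alveolar macrophages, 1281 endothelial cells, 765 fibroblasts (a class that also carried pericyte markers), 271 lung epithelial cells, 217 neutrophils and 103 NK cells were found. LSN+PD-L1 27 held 1864 of the macrophages and monocytes. Tumour cells in all libraries carried transcripts of the genes that define the model, with Rb1 at 21.2 to 40.0 CPM, Trp53 at 12.1 to 35.0 CPM and Rbl2 at 4.59 to 16.9 CPM. Reads from 5' libraries need not cover the deleted part of a gene.

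Tumour cells made up 47.5% ± 25.3 (SD, n = 5) of the cells in LSN-treated libraries and 74.2% ± 9.88 (n = 4) in the others (exact permutation p = 0.0635). By PD-L1 treatment they made up 48.9% ± 25.7 against 72.4% ± 13.8 (exact permutation p = 0.111). T cells made up 11.4% ± 7.99 against 3.96% ± 1.48 by LSN treatment (exact permutation p = 0.0794) and 11.1% ± 8.13 against 4.35% ± 2.55 by PD-L1 treatment (p = 0.143). B cells stood at 11.6% ± 10.2 against 3.11% ± 1.57 by LSN treatment (exact permutation p = 0.127) and 10.2% ± 10.4 against 4.82% ± 5.45 by PD-L1 treatment (p = 0.333). Macrophages and monocytes stood at 11.3% ± 12.9 against 4.54% ± 2.51 (exact permutation p = 0.286) and 11.7% ± 12.7 against 4.07% ± 1.79 (p = 0.111). Without LSN+PD-L1 27 the differences by LSN treatment fell to -16.2 percentage points for tumour cells, 4.64 for T cells, 4.41 for B cells and 1.02 for macrophages and monocytes, and those by PD-L1 treatment to -12.7, 3.87, 0.991 and 1.97. PD-L1-treated libraries held 1.42% ± 1.13 neutrophils against 0.351% ± 0.350 (exact permutation p = 0.0317) and 0.542% ± 0.263 NK cells against 0.166% ± 0.111 (p = 0.0476). The neutrophil difference fell from 1.07 to 0.568 points without PD-L1 09 (exact permutation p = 0.0571). No share passed adjustment over the 20 tests, in which the lowest adjusted p was 0.357. Of the T cells, 51.2% ± 8.69 in LSN-treated and 49.0% ± 13.4 in other libraries had a Cd8a or Cd8b1 UMI (exact permutation p = 0.762), and 46.5% ± 9.02 against 54.8% ± 11.1 by PD-L1 treatment (p = 0.238; -8.35 points, or -4.85 without Vehicle 24 and -13.4 without LSN 26). The same share among B cells, which should lack these genes, was 0% to 2.94%, at median depths of 1485 to 5895 UMIs in B cells and 1757.5 to 4811 in T cells. Differences of a few percent in a library of few T cells were not detectable at this depth, since PD-L1 09 held 56 and LSN 13 held 75.

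**Figure D1:**
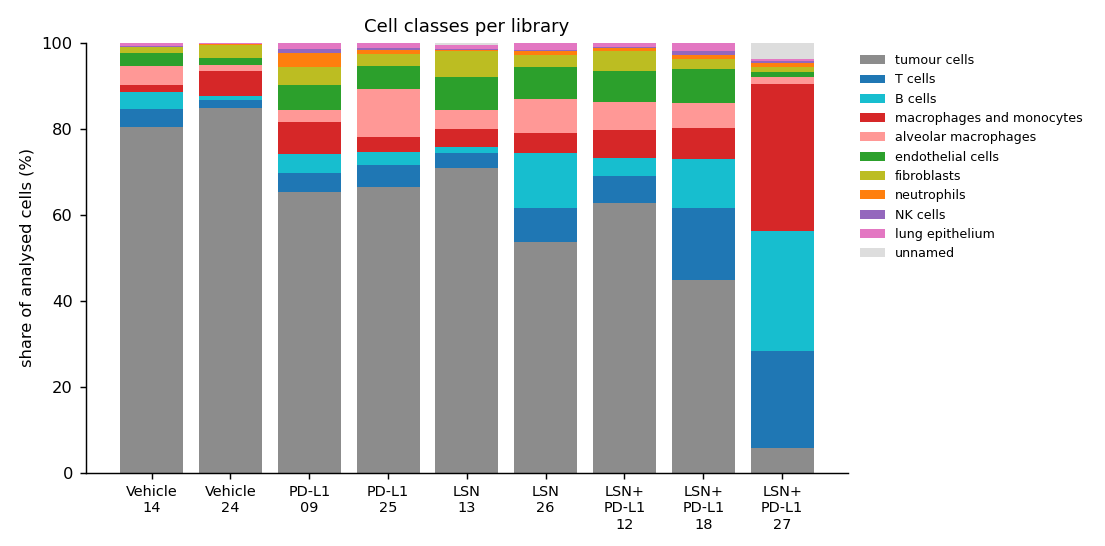
Stacked bars give the percent of each library's analysed cells (vertical axis, %) in each named class, with libraries of the 4 groups side by side on the horizontal axis. LSN+PD-L1 27 stands apart, with 34.3% macrophages and monocytes and few tumour cells.

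Tumour cells of LSN-treated libraries carried more mitotic RNA. Genes of the mitosis list took 0.551% ± 0.114 (SD, n = 5) of tumour-cell UMIs with LSN and 0.343% ± 0.0850 (n = 4) without it (difference 0.208 percentage points, two-sided exact permutation p = 0.0317). The group means were 0.391% ± 0.0430 with vehicle (n = 2), 0.295% ± 0.103 with PD-L1 blockade (n = 2), 0.505% ± 0.158 with LSN (n = 2) and 0.581% ± 0.101 with the combination (n = 3). Without LSN, libraries stood at 0.222% in PD-L1 09 and 0.360% to 0.421% in the others. With it they ran from 0.393% in LSN 26 to 0.689% in LSN+PD-L1 18. The difference was 0.229 among female and 0.201 among male libraries. It was 0.302 in the 5 libraries of shorter barcode lists and 0.0768 in the 4 of longer ones, sets too small for a p below 0.05. Leaving out a single library gave an exact permutation p above 0.05 without Vehicle 24 (difference 0.214, p = 0.0714), PD-L1 09 (0.168, p = 0.0714), or PD-L1 25 (0.216, p = 0.0714). The exact permutation p was 0.0571 without LSN 13 (0.191), LSN+PD-L1 12 (0.204), LSN+PD-L1 18 (0.173) or LSN+PD-L1 27 (0.224). The exact permutation p stayed below 0.05 without Vehicle 14 (0.234, p = 0.0357) or LSN 26 (0.247, p = 0.0286). Without the tumour cluster rich in hemoglobin RNA, mostly cells of Vehicle 24, it was 0.170 (exact permutation p = 0.0952, in a range of 0.0159 to 0.333 over the settings run). Seen only after clustering, 1 tumour cluster of low UMI counts and high mitotic RNA (923 cells, median 1593 UMIs) held 5.69% to 22.9% of the tumour cells in LSN-treated libraries and 0.922% to 2.25% in the others.

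**Figure D2:**
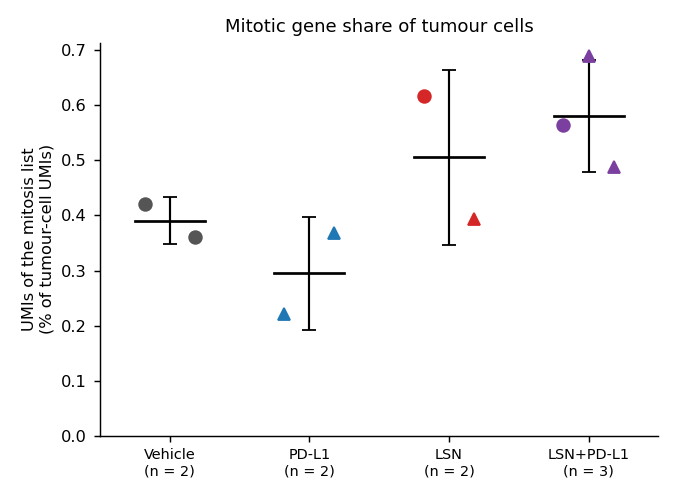
Each point is the percent of tumour-cell UMIs on genes of the mitosis list (vertical axis, %) in 1 library, by treatment group (horizontal axis), with group means and SD bars, circles for male and triangles for female mice. The 3 combination libraries lie between 0.488% and 0.689%, and all 4 libraries without LSN lie at or below 0.421%.

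All 33 tested members of the mitosis list had a higher fitted level with LSN, with a median log2 fold change of 0.70. The list rose as a group (camera adjusted p = 2.90e-23). With an estimated correlation its p was 0.0652. Within the list, 22 members had an unadjusted p below 0.05, 20 passed when adjusted over the list alone and 0 passed over all genes. Aurka, the kinase that LSN was taken to inhibit (ENSMUSG00000027496, chromosome 2, 172356190 to 172370535), had 95.2 ± 19.7 CPM with LSN and 44.6 ± 6.02 without (log2 fold change 1.06, SE 0.16, unadjusted p = 0.000134, adjusted p = 0.750). All 5 LSN-treated libraries lay above the other 4. Plk1, a kinase of mitotic entry (chromosome 7, 122159439 to 122169873), had 99.4 ± 22.1 against 56.7 ± 15 CPM (0.83, adjusted p = 0.847). Ccnb1, the cyclin of mitotic entry (chromosome 13, 100778650 to 100786570), had 194 ± 42.5 against 110 ± 45.6 CPM (0.86). Pif1, a helicase gene, had 29.3 ± 10.4 against 10.7 ± 2.65 CPM (1.39). Cenpa, the histone variant of centromeres, had 300 against 143 CPM (1.04). Mki67, a general mark of cycling cells, stood at 448 and 424 CPM (0.09), and Aurkb at a log2 fold change of -0.08. The wider G2 and M phase list rose too, with 46 of 54 members higher (median 0.48, camera adjusted p = 3.00e-14, 2 past 0.05 adjusted over the list alone). Its p with an estimated correlation was 0.163. The S phase list fell slightly, with 32 of 43 members lower (median -0.10, adjusted p = 0.0235, estimated-correlation p = 0.50). Fen1 (-0.54) and Hells (-0.48), genes of DNA replication and chromatin, had its smallest p. The mitosis median was 0.93 in the shorter and 0.26 in the longer barcode set. That of the G2 and M phase list was 0.75 and 0.010, and in the longer set its call was lost. The S phase call ended without Vehicle 14 (-0.071), PD-L1 25 (0.0092), LSN 26 (-0.021) or LSN+PD-L1 27 (-0.068), and with sex as a term (-0.099). It also ended in the shorter barcode set (-0.023), within either sex and without the low-UMI (-0.076) or the hemoglobin-rich tumour cluster (-0.056).

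**Figure D3:**
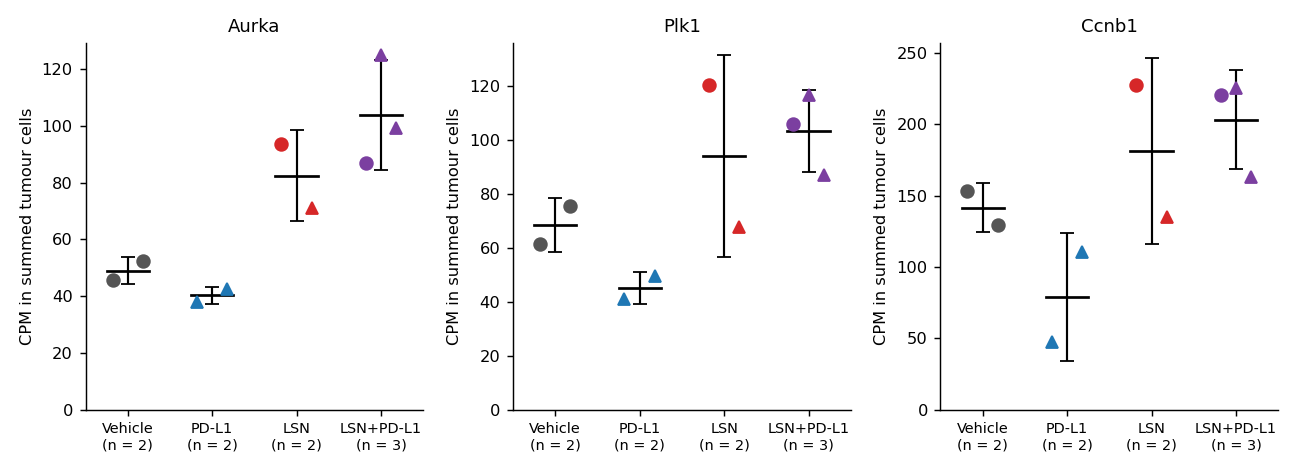
CPM of Aurka, Plk1 and Ccnb1 in summed tumour cells (vertical axes) is drawn per library and treatment group (horizontal axes), with group means and SD bars, circles for male and triangles for female mice. Aurka lies between 71.1 and 125 CPM in the 5 LSN-treated libraries and between 38.0 and 52.3 CPM in the other 4.

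Counted by cells, 31.3% ± 5.88 (SD, n = 5) of tumour cells of at least 2000 UMIs were mitotic-high with LSN and 25.7% ± 7.72 (n = 4) without (exact permutation p = 0.286). The difference was 5.55 points, 2.16 without PD-L1 09, 1.85 without the low-UMI cluster, 2.64 without the hemoglobin-rich one, and 10.5 in the shorter and -1.08 in the longer barcode set. That limit left out 74 to 431 tumour cells per LSN-treated and 41 to 280 per other library. The lowest library was PD-L1 09 (118 of 758 cells, 15.6%, Wilson 95% interval 13.2 to 18.3) and the highest LSN+PD-L1 18 (394 of 1053 cells, 37.4%, 34.5 to 40.4). With all tumour cells, thinned to 1000 UMIs, and at least 3 mitotic UMIs, the difference was 12.4 percentage points (exact permutation p = 0.0476, in a range of 0.0476 to 1.0 over the settings run).

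Interferon and MHC class I genes of tumour cells did not pass with LSN. Genes of the type I interferon response list took 0.125% ± 0.0465 (n = 5) against 0.106% ± 0.0402 (n = 4) of tumour-cell UMIs (exact permutation p = 0.587). Interferon gamma response genes took 0.0808% against 0.0865% (exact permutation p = 0.698) and MHC class I genes 0.502% ± 0.0919 against 0.443% ± 0.0783 (p = 0.397, a difference of 0.0591 that fell to 0.0239 without Vehicle 14 and 0.0218 without LSN+PD-L1 27). Of 37 tested type I interferon members 24 were higher (median log2 fold change 0.11, camera adjusted p = 0.199). The interferon gamma list had a median of -0.14 and a mean of 0.09 (adjusted p = 0.977). The MHC class I list had -0.05 and 0.07 (adjusted p = 0.497). In both the test leaned to the mean's side. Isg15 stood at 0.11, Ifit3 at 0.26, Cxcl10 at -0.38, H2-K1 at 0.20, H2-D1 at 0.014 and Cd274, the gene of PD-L1, at -0.42. B2m, the light chain of MHC class I, had 402 ± 151 against 197 ± 53.8 CPM (0.96, unadjusted p = 0.0104, adjusted p = 0.847), higher than the mean of the others in 5 of 5 libraries.

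Genes of 4 immune cell lists were higher in the tumour cells of LSN-treated libraries. MHC class II genes rose (6 of 7 higher, median 2.03, camera adjusted p = 4.91e-05, estimated-correlation p = 0.0952, 3 past 0.05 adjusted over the list alone). H2-Ab1 stood at 12.4 against 2.01 CPM (2.46) and H2-Aa at 2.12. T cell cytotoxicity genes rose (6 of 7 higher, median 1.95, adjusted p = 4.92e-05, estimated-correlation p = 0.0163, 4 over the list alone). The chemokine genes Ccl4, at 2.62 against 0.289 CPM (2.92), and Ccl3 (2.76) were among them. Tissue repair macrophage genes rose (7 of 11 higher, median 1.14, adjusted p = 3.36e-05, estimated-correlation p = 0.00499, 4 over the list alone). Of the complement genes, C1qb stood at 13.3 against 2.58 CPM (2.37) and C1qc at 2.81. Inflammatory macrophage genes had a median of 0.13 and a mean of 1.23 (5 of 7 higher, adjusted p = 0.0118, estimated-correlation p = 0.116, 2 over the list alone). Free RNA estimated from nearly empty droplets would give 204% of the tumour-cell level of Ccl4 and 240% of that of C1qb, against 1.63% for Aurka and 9.30% for B2m. The inflammatory call ended without Vehicle 14 (0.58), PD-L1 25 (0.21) or LSN+PD-L1 27 (-0.28), among male libraries (-0.36) and in the shorter (-0.21) and longer barcode set (0.077). The median of tissue repair genes was 2.21 without Vehicle 14 and 0.61 without LSN 26, and that of MHC class II genes 1.34 without LSN+PD-L1 27.

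Dissociation and heat stress genes fell with LSN (14 of 17 lower, median -0.39, camera adjusted p = 0.000131, estimated-correlation p = 0.141), with the early response genes Fosb at -0.82 and Fos at -0.70. That call ended without Vehicle 14 (-0.31) and in the longer barcode set (0.053). The median was -0.64 without LSN+PD-L1 27. Neuroendocrine genes (median -0.12, adjusted p = 0.389), with Chga at -0.30, non-neuroendocrine genes (-0.17, 0.420), apoptosis (-0.0021, 0.780) and hypoxia and glycolysis (-0.13, 0.199) did not pass. Nucleic acid sensing genes had a median of -0.0017 and a mean of 0.18 (adjusted p = 0.199, the test on the mean's side), T cell exhaustion genes 0.22 (0.0628), naive and memory T cell genes 0.0096 (0.680) and regulatory T cell genes -0.12 (0.576).

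Gene by gene, edgeR called 0 of 15729 tested genes for the LSN effect, with 908 at an unadjusted p below 0.05 and 54 called by DESeq2, which in simulated tumour data called 34 unchanged genes (edgeR 8). Of those 54, 32 were higher and 22 lower. Besides Aurka and Pif1, the smallest p belonged to Pyy (log2 fold change -3.15), the RNA gene Snhg11 (-3.32, 16.3 against 129 CPM), Rasa4 (-1.91), Sct (-3.45), Sp9 (-2.94), Cdh7 (-5.21), Pcdhb6 (2.45) and Ccl4. Pyy, peptide YY, and Sct, secretin, are peptide hormone genes of endocrine cells. The adjusted p of all 10 was 0.750. Of the model's genes, Rb1 stood at -0.20, Trp53 at 0.11 and Rbl2 at 0.43.

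**Figure D4:**
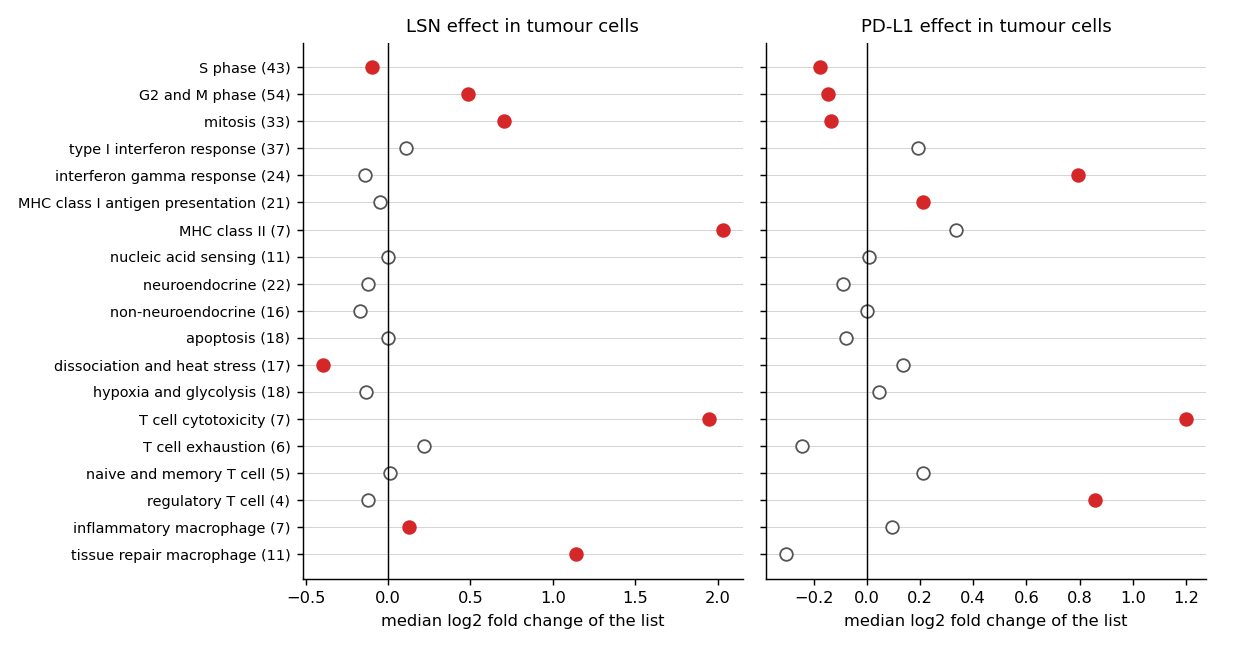
Median fitted log2 fold changes (horizontal axis) of the 19 gene lists (vertical axis, tested members in brackets) in tumour cells are drawn for the LSN effect and the PD-L1 effect, with filled red points where the camera adjusted p was below 0.05. The mitosis list lies at 0.70 for LSN and at -0.14 for PD-L1.

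PD-L1 blockade went with higher interferon gamma response genes in tumour cells (20 of 24 higher, median log2 fold change 0.79, camera adjusted p = 0.000756, estimated-correlation p = 0.249). The GTPase genes Iigp1 and Gbp2 stood at 3.66 and 2.71. MHC class I genes rose (18 of 21 higher, median 0.21, adjusted p = 0.00511, estimated-correlation p = 0.262). Nlrc5, their transactivator, stood at 0.61 and the chaperone gene Pdia3 at 0.30. T cell cytotoxicity genes rose (7 of 7 higher, median 1.2, adjusted p = 0.000885, estimated-correlation p = 0.0285, 1 over the list alone), with Nkg7 at 1.97 and Ccl5 at 3.66. Regulatory T cell genes rose (4 of 4 higher, median 0.86, adjusted p = 0.0154, estimated-correlation p = 0.0468), with Ikzf2 at 2.47 and Tnfrsf4 at 1.39. S phase genes fell slightly (39 of 43 lower, median -0.18, adjusted p = 5.11e-05, estimated-correlation p = 0.243), with Gmnn at -0.40 and Cdc6 at -0.43. So did G2 and M phase (45 of 54 lower, -0.15, adjusted p = 0.000454, estimated-correlation p = 0.438; Gas2l3 -0.47, Anp32e -0.60) and mitosis genes (24 of 33 lower, -0.14, adjusted p = 0.0393, estimated-correlation p = 0.598; Hmmr -0.39, Depdc1a -0.44). With sex as a term none of the 19 lists passed: the interferon gamma median was 0.51, MHC class I 0.22, T cell cytotoxicity 0.27, regulatory T cell 0.30, S phase -0.031, G2 and M phase 0.038 and mitosis 0.041. The interferon gamma call also ended without Vehicle 14 (0.65), PD-L1 09 (0.093) or LSN+PD-L1 27 (0.48). It was lost in the 4 libraries of longer barcode lists too (0.61, against 0.98 in the shorter set). MHC class I lost its call without Vehicle 14 (0.077), PD-L1 09 (0.094), LSN 26 (0.19) or LSN+PD-L1 27 (0.11) and in the longer set (0.14). Regulatory T cell genes lost it without Vehicle 14 (0.67), PD-L1 25 (0.87), LSN 13 (0.80), LSN+PD-L1 12 (0.79) or the low-UMI tumour cluster (0.70) and in the longer set (0.35). Ikzf2 turned to -0.98 with sex as a term and ran from -0.94 to 3.67 with single libraries left out. The S phase call ended without Vehicle 14 (-0.095) or PD-L1 09 (-0.076) and in the longer set (0.036). That of G2 and M phase ended without Vehicle 14 (-0.10), PD-L1 09 (0.027) or LSN 13 (0.022). That of mitosis ended without Vehicle 14 (-0.075), PD-L1 09 (0.056), LSN 13 (0.035), LSN+PD-L1 12 (-0.12) or LSN+PD-L1 27 (-0.076). In the longer set these 2 lists were called as higher (0.14 and 0.18). Free RNA would give 154% of the tumour-cell level of Ccl5, 75.9% of that of Nkg7, 72.9% of Gbp2 and 43.0% of Iigp1 over all libraries.

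Type I interferon response genes had a median of 0.19 by PD-L1 treatment (26 of 37 higher, adjusted p = 0.380), MHC class II genes 0.33 (0.511), nucleic acid sensing 0.0096 (0.557), neuroendocrine -0.088 (0.50), and non-neuroendocrine genes -0.0011 (0.669), with adjusted p in parentheses. The medians were -0.080 for apoptosis (0.646), 0.13 for stress (0.250) and 0.045 for hypoxia and glycolysis (0.781). They were -0.24 for T cell exhaustion (0.756), 0.21 for naive and memory T cell (0.557), 0.093 for inflammatory macrophage (0.542) and -0.30 for tissue repair macrophage genes (0.50). As shares of tumour-cell UMIs, type I interferon genes took 0.127% against 0.103% (exact permutation p = 0.460; difference 0.0234, or 0.010 without Vehicle 14 and 0.00399 without LSN+PD-L1 27). Interferon gamma genes took 0.0885% against 0.0768% (exact permutation p = 0.492; 0.0118, or without Vehicle 24 0.0185, PD-L1 09 0.00186, PD-L1 25 0.0218, LSN+PD-L1 12 0.0178 and LSN+PD-L1 27 0.00189). MHC class I genes took 0.515% ± 0.0878 against 0.427% ± 0.0630 (exact permutation p = 0.127; 0.0880, or 0.0582 without Vehicle 14 and 0.0540 without LSN+PD-L1 27). Ifit3 had 3.23 CPM with PD-L1 blockade (n = 5) against 0.464 without (n = 4), a log2 fold change of 2.66 (edgeR unadjusted p = 0.0112), while Cd274 stood at 0.74. Further values were 0.40 for Isg15, 0.27 for B2m, 0.25 for H2-K1, 0.32 for H2-D1 and 0.093 for Cxcl10. Aurka stood at 0.025, Aurkb at -0.39, Plk1 at -0.23, Ccnb1 at -0.34, Mki67 at -0.14, Chga at 0.20, Rb1 at -0.13, Trp53 at 0.040 and Rbl2 at -0.062.

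For the PD-L1 effect edgeR called 0 genes (381 at an unadjusted p below 0.05) and DESeq2 called 10. The smallest p (adjusted p = 0.0789) went to Gm47283 (chromosome Y, 90784738 to 90816464) and Ooep, an egg-cell gene. Both were higher in 5 of 5 libraries. Gm47283 had 28.6 ± 12.2 against 6.02 ± 2.43 CPM (log2 fold change 2.32) and Ooep 24 ± 5.82 against 6.35 ± 4.14 CPM (2.19). With sex as a term they stood at 2.36 and 2.24. The others, all at an adjusted p of 1.0, were Trim29 (3.28), Ccl5, Tubb2b (-1.17), Ablim3 (2.30), Wnt5a (1.86), AA467197 (2.25), Snx10 (1.78) and the X-linked Xlr3b (3.82). With 4 of 5 treated and 1 of 4 other libraries female, PD-L1 blockade and sex overlapped, and Gm47283 reads need not stem from Y.

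Tumour cells of the combination were compared with vehicle (3 libraries against 2). Mitosis genes rose (33 of 33 higher, median 0.60, camera adjusted p = 1.98e-12, estimated-correlation p = 0.148, 1 over the list alone). Aurka stood at 104 ± 19.3 against 49.0 ± 4.78 CPM (1.08), Cenpa at 1.06 and Pif1 at 1.40. G2 and M phase genes rose (40 of 54 higher, 0.33, 0.000146, estimated-correlation p = 0.433). S phase genes fell (38 of 43 lower, -0.32, 1.73e-06, estimated-correlation p = 0.207; Cdc6 -0.97, Gmnn -0.73). Interferon gamma genes (19 of 24 higher, 0.70, 0.0172, estimated-correlation p = 0.411; Cxcl9 5.44, Cd74 1.97) and MHC class I genes (16 of 21, 0.11, 0.0118, estimated-correlation p = 0.312; B2m 1.24, Pdia3 0.67) rose. MHC class II genes rose (7 of 7, 2.10, 3.18e-05, estimated-correlation p = 0.0901, 1 over the list alone; H2-Ab1 2.69, H2-Aa 2.10), and so did T cell cytotoxicity genes (7 of 7, 3.16, 1.09e-07, estimated-correlation p = 0.00556, 4 over the list alone; Ccl4 3.16, Ccl3 3.42, Ccl5 5.45). Inflammatory macrophage (4 of 7, median 0.21, mean 1.44, 0.0131, estimated-correlation p = 0.124, 3 over the list alone) and tissue repair macrophage genes (8 of 11, 1.21, 0.00132, estimated-correlation p = 0.0140; C1qc 2.73, C1qb 2.07) rose. Stress genes fell (12 of 17 lower, -0.42, 0.0246, estimated-correlation p = 0.338; Fos -0.78, Nr4a1 -0.99). Type I interferon response genes were higher in 27 of 37 (0.25, adjusted p = 0.0544). The other lists had medians of -0.12 to 0.13 and adjusted p of 0.120 to 0.490. Without LSN+PD-L1 27, the calls for interferon gamma (0.10), MHC class I (-0.073) and inflammatory macrophage genes (-0.53) ended. The MHC class II median was then 1.06. Without Vehicle 14 those for S phase (-0.16), interferon gamma (0.45), MHC class I (-0.16) and stress (-0.010) ended. Without Vehicle 24 that for G2 and M phase ended (0.23), and without LSN+PD-L1 12 (-0.23) or 18 (-0.21) that for stress. Those for S phase (-0.13), interferon gamma (0.48) and inflammatory macrophage genes (0.032) ended with sex as a term. Without the hemoglobin-rich tumour cluster those for G2 and M phase (0.13) and interferon gamma (0.60) ended, and the mitosis median was 0.28, still called. Without the low-UMI cluster those for stress (-0.36) and inflammatory macrophage genes (-0.062) ended. Free RNA would give 253% of the tumour-cell level of Cxcl9, 123% of Cd74, 181% of H2-Ab1 and 228% of C1qc over all libraries.

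No gene passed in the other tumour-cell comparisons by edgeR, which gave 0 calls each. The interaction had 392 genes at an unadjusted p below 0.05 (DESeq2 6), LSN versus vehicle 607 (19), PD-L1 versus vehicle 663 (23), combination versus vehicle 586 (7), versus LSN 195 (2) and versus PD-L1 718 (31). Smallest p for the interaction went to Emx1 (-5.91), Clmn (-1.33), Necab2 (5.08), Vcan (3.93), Sp9 (5.08), Lgals1 (5.44), Capn2 (-1.07), Slc24a3 (-2.53), Ccdc36 and Shroom1. LSN versus vehicle put first Sp9 (-5.48), Sct (-5.53), Capn2 (0.93), Ooep (-1.72), Clmn (1.01), Nedd9 (0.84), Igfbp5 (1.86) and Tnr (1.64). To these came Actc1 (0 and 0.139 CPM with LSN, 3.24 and 5.34 with vehicle) and Ccdc36 (0.155 and 0 against 3.49 and 5.93 CPM). PD-L1 versus vehicle put first Gm47283 (3.25, adjusted p = 0.170), Tubb2b (-2.20), Sp9 (-4.42), Klhdc8a (1.49), Slc24a3 (2.17), Clmn (0.98), Adgrv1 (-1.45), Trim29 (4.2), Ooep (1.53) and Shroom1 (3.35 and 1.23 against 0.0612 and 0.0737 CPM). It compared 2 female with 2 male mice, so treatment and sex cannot be told apart. Against vehicle, the combination had Gm47283 (2.27), Sp9 (-4.83), Disp2 (0.90), Gsn (1.10), Ccl5, Aurka, Ablim3 (3.28), Pyy (-3.31), Ccl4 and Gjc1 (-3.20). Against LSN it had Ooep (2.86, adjusted p = 0.352), Bvht (2.87), Rspo1 (-3.85), Gm47283 (1.39), Nedd9 (-0.67), Gnb3 (2.47), Snx10 (2.20), Spred1 (2.05), Actc1 and Ccdc36. Against PD-L1 blockade it had Aurka (1.37, adjusted p = 0.965), Pif1 (1.94), Ccl4 (4.19), C1qb (3.64), Emx1 (-4.44), Miip (1.18), Pnrc2 (1.01), Rasa4 (-2.04), Wfdc17 (3.74) and Schip1 (1.08).

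In T cells, PD-L1 blockade went with a rise of exhaustion genes (9 of 10 higher, median log2 fold change 0.97, camera adjusted p = 6.21e-05, estimated-correlation p = 0.0478, 7 past 0.05 adjusted over the list alone). Receptor genes that restrain T cells led it. Tigit had 398 ± 148 CPM with blockade (n = 5) and 207 ± 44.7 without (n = 4), a log2 fold change of 0.96. Pdcd1, the receptor of PD-L1, had 348 ± 100 against 201 ± 48.0 CPM (0.82) and Ctla4 263 against 133 CPM (0.98). Naive and memory T cell genes fell (8 of 8 lower, median -0.50, adjusted p = 6.21e-05, estimated-correlation p = 0.0453, 2 over the list alone), with Il7r at -0.52 and Tcf7 at -0.48. Cytotoxicity genes rose (13 of 14 higher, 0.55, 0.000529, estimated-correlation p = 0.147, 1 over the list alone; the granzyme genes Gzmb 1.12 and Gzmk 1.12). Regulatory T cell genes rose (6 of 6, 0.40, 0.0127, estimated-correlation p = 0.137, 2 over the list alone; Tnfrsf4 1.12). So did type I interferon response (29 of 34, 0.30, 6.21e-05, estimated-correlation p = 0.110, 2 over the list alone; Zbp1 0.81, Ifi27l2a 0.75) and interferon gamma response (18 of 22, 0.38, 0.000251, estimated-correlation p = 0.0753, 0 over the list alone; Jak2 0.76, Igtp 0.71) genes. Named genes had an adjusted p of 0.541 to 0.559 over all genes. S phase (-0.0074, 0.996), G2 and M phase (-0.15, 0.224) and mitosis genes (-0.20, 0.580) did not pass. With sex as a term the exhaustion median was 0.63 and the naive and memory median -0.26, both still called. The regulatory T cell call ended then (0.22), as it did without Vehicle 24 (0.49), PD-L1 25 (0.27) or LSN 13 (0.39), and in the shorter barcode set (0.31). The type I interferon call ended without Vehicle 14 (0.21), and the cytotoxicity call in the 5 libraries of shorter barcode lists (0.19, against 0.72 in the longer set).

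LSN treatment went with higher cell cycle genes in T cells too. Mitosis genes rose (8 of 8 higher, median 1.08, camera adjusted p = 2.03e-06, estimated-correlation p = 0.0923, 1 over the list alone), led by Ube2c, of the mitotic ubiquitin machinery (54.8 against 11.0 CPM, 2.25, unadjusted p = 0.000354), and by Birc5 (1.42). G2 and M phase genes rose (18 of 23, median 0.30, 9.89e-06, estimated-correlation p = 0.197). Over the list alone 1 higher and 1 lower member passed, the latter Lbr at -0.53. S phase genes rose too (16 of 23, 0.19, 0.0167, estimated-correlation p = 0.321; Prim1 1.38, Hells -0.51). Type I interferon response genes rose (29 of 34, 0.35, 2.03e-06, estimated-correlation p = 0.0680). Of its antiviral genes, Bst2 stood at 442 against 292 CPM (0.55) and Isg15 at 552 against 344 CPM (0.66). Exhaustion genes were just past the threshold (8 of 10 higher, 0.26, 0.0499, estimated-correlation p = 0.256; Nr4a2 0.39, Entpd1 1.04). Cytotoxicity (-0.071, 0.598), naive and memory (-0.015, 0.846), regulatory T cell (0.11, 0.152) and interferon gamma genes (0.063, 0.491) did not pass. Of 5422 genes edgeR called 0 for LSN (237 at an unadjusted p below 0.05; DESeq2 0) and 0 for PD-L1 (426; DESeq2 3). The type I interferon call ended without Vehicle 14 (0.23), and the mitosis median was 2.63 without Vehicle 14 and 2.01 without PD-L1 25. In the longer barcode set the mitosis median was 0.48 and in the shorter set 1.40. The S phase call ended without Vehicle 24 (0.13), PD-L1 09 (0.20), LSN 13 (0.093) or LSN+PD-L1 12 (0.087), among female libraries (0.0022) and in the longer set (0.052), where that of G2 and M phase ended too (0.024). The exhaustion call ended without Vehicle 24 (0.20), PD-L1 25 (0.077), LSN 13 (0.34), LSN 26 (0.22) or LSN+PD-L1 27 (0.077), within either sex, with sex (0.14) or barcode set (0.18) as a term and in the shorter set (-0.015).

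Macrophages and monocytes of PD-L1-treated libraries had more RNA of Cxcl9, a chemokine gene induced by interferon gamma that attracts T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079). It had 269 ± 56.1 CPM (SD, n = 5) against 61.4 ± 10.5 (n = 4), a log2 fold change of 2.10 (SE 0.24, edgeR adjusted p = 0.0267). All 5 treated libraries lay above the other 4. Interferon gamma response genes rose (24 of 25 higher, median 0.97, camera adjusted p = 1.35e-08, estimated-correlation p = 0.0522, 11 past 0.05 adjusted over the list alone), Gbp2 among them (2.49). MHC class I genes rose (20 of 21 higher, 0.69, 3.02e-11, estimated-correlation p = 0.0533, 10 over the list alone). The peptide transporter genes Tap1 and Tap2 stood at 1.07 and 0.87. Type I interferon response genes rose as well (36 of 37, 0.62, 4.24e-10, estimated-correlation p = 0.133, 1 over the list alone; Isg15 1.15, Ifi27l2a 1.05). Inflammatory macrophage genes (11 of 13, 0.62, 0.0222, estimated-correlation p = 0.142, 1 over the list alone; Nos2 4.79) and mitosis genes (13 of 20, 0.15, 0.0360, estimated-correlation p = 0.366; Ccnb1 0.90, Knstrn 0.88) rose. Tissue repair (-0.23, 0.0815), MHC class II (0.12, 0.201), S phase (-0.12, 0.976) and G2 and M phase genes (0.057, 0.159) did not pass. The Cxcl9 call ended without Vehicle 24 (2.31), PD-L1 09 (2.14), LSN 13 (2.14), LSN 26 (2.08) or LSN+PD-L1 18 (2.08), and with sex as a term (1.83). It also ended with alveolar macrophages included (1.64), within the 1 macrophage cluster with at least 20 cells in each library (2.40) and in the shorter (2.08) and longer barcode set (2.21). The interferon gamma median was 0.34 without PD-L1 09, 0.98 in the shorter and 0.65 in the longer barcode set. The MHC class I median was 0.45 without Vehicle 24, and the type I interferon median 0.37 without Vehicle 24 and 0.37 without PD-L1 09, all still called. The inflammatory call ended without Vehicle 24 (0.44), PD-L1 25 (0.37), LSN 26 (0.48) or LSN+PD-L1 12 (0.26), in the shorter set (0.050) and within the 1 cluster (0.49). The mitosis call ended without Vehicle 14 (0.17), PD-L1 25 (0.091), LSN 13 (0.060), LSN+PD-L1 18 (0.17) or LSN+PD-L1 27 (0.12) and turned with sex as a term (-0.19). With alveolar macrophages included the list was called as lower (-0.40).

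**Figure D5:**
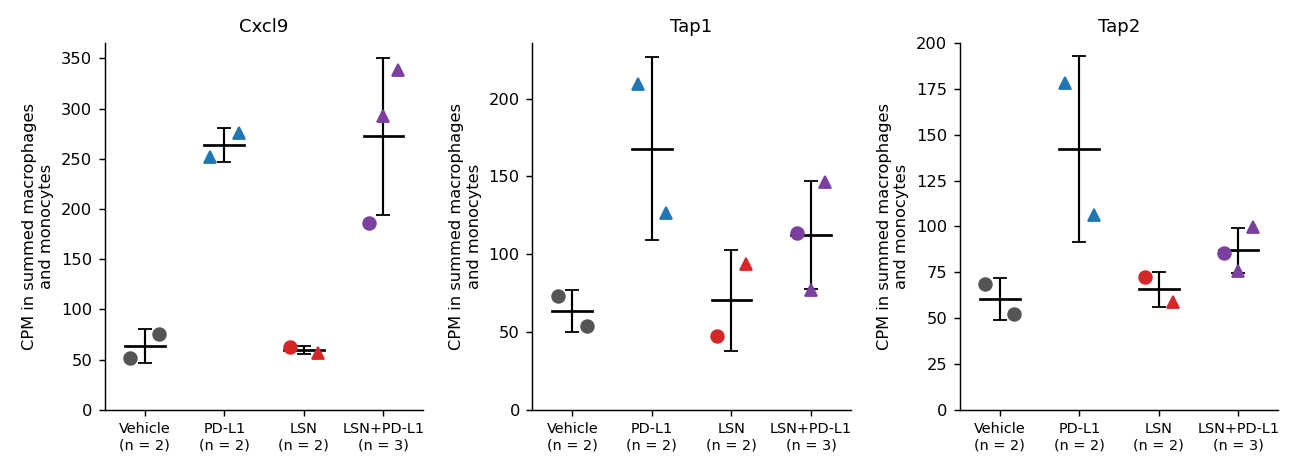
CPM of Cxcl9, Tap1 and Tap2 in summed macrophages and monocytes (vertical axes) is drawn per library and treatment group (horizontal axes), with group means and SD bars, circles for male and triangles for female mice. Cxcl9 lies between 186 and 339 CPM in the 5 PD-L1-treated libraries and between 51.4 and 75.6 CPM in the other 4.

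With LSN, 2 macrophage genes passed in edgeR (459 at an unadjusted p below 0.05; DESeq2 called 20). Ifitm1, an interferon-induced membrane protein gene (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), fell from 128 ± 58.0 to 10.5 ± 5.31 CPM (log2 fold change -3.28, SE 0.39, adjusted p = 0.0191, lower in 5 of 5 libraries). Apoc1, an apolipoprotein gene (chromosome 7, 19689481 to 19692660), rose from 30.7 ± 31.8 to 204 ± 98.6 CPM (2.76, SE 0.30, adjusted p = 0.0154, higher in 5 of 5). For PD-L1, Cxcl9 was the 1 gene that passed of 8216 tested (426 at an unadjusted p below 0.05; DESeq2 called 6). Type I interferon response genes rose with LSN (35 of 37 higher, median 0.62, camera adjusted p = 9.83e-10, estimated-correlation p = 0.135, 0 over the list alone; Lgals3bp 0.75, Bst2 0.72). The median was 1.5 among male and -0.23 among female libraries, 0.19 in the shorter barcode set, where the call ended, and 0.75 in the longer. It also ended without Vehicle 24 (0.35). Interferon gamma (0.11, 0.199), MHC class I (0.13, 0.199), MHC class II (0.30, 0.156), inflammatory (0.34, mean 0.023, 0.661) and mitosis genes (0.14, 0.559) did not pass. Nor did tissue repair genes (median 0.17, mean -0.20, tested as higher, 0.199), S phase (0.055, tested as lower, 0.310) or G2 and M phase genes (median -0.017, mean 0.015, tested as lower, 0.262). The Ifitm1 call ended without PD-L1 25 (-3.15), LSN 13 (-3.07), LSN 26 (-3.87) or LSN+PD-L1 12 (-3.27). That of Apoc1 ended without PD-L1 25 (2.61), LSN 13 (2.86) or LSN 26 (2.65), and both ended with sex as a term (-3.41 and 2.73), with alveolar macrophages included (-2.87 and 1.97), in the longer barcode set (-2.91 and 2.08) and among female (-3.64 and 4.51) or male libraries (-3.12 and 1.58). Apoc1 stood at 0.22 within the 1 macrophage cluster with at least 20 cells in each library and at 3.68 in the shorter barcode set, without a call in either, while Ifitm1 kept its call in the latter (-4.11). In that 1 cluster Ifitm1 had 0 to 26 UMIs per library, too few to be tested. The mix of clusters differed by LSN treatment. A cluster marked by Ccr2 and Ly6c2 made up 7.98% to 17.8% of the class with LSN against 4.17% in Vehicle 24 and 39.6% to 46.8% in the other 3. A low-UMI cluster with Apoc1 among its markers made up 18.1% to 74.2% against 15.1% to 24.7%.

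In B cells 1 gene passed for each treatment, both antibody gene segments, named here after their values had been seen. Igkv17-127 had 363 ± 328 against 2.94 ± 3.48 CPM by LSN treatment (log2 fold change 6.79, edgeR adjusted p = 0.0106, higher in 5 of 5 libraries). Ighv2-2 had 16.8 ± 11.5 against 200 ± 121 CPM by PD-L1 treatment (-4.43, adjusted p = 0.00690, lower in 5 of 5). The Igkv17-127 call ended without Vehicle 14 (9.07) or Vehicle 24 (6.60, or 6.52 with LSN+PD-L1 27 out too), among male libraries (6.87) and in the shorter barcode set (7.54). That of Ighv2-2 ended without Vehicle 14 (-4.16) or LSN 26 (-3.66) and in the shorter (-3.57) and longer set (-3.35), with -6.80 without PD-L1 25. Of 4600 genes, 161 and 311 had an unadjusted p below 0.05, and DESeq2 called 2 and 4. In endothelial cells (9140 genes) edgeR called 0 for LSN and 0 for PD-L1, with 468 and 622 at an unadjusted p below 0.05 and 12 and 32 called by DESeq2. In fibroblasts (8780 genes) edgeR called 0 and 0, with 277 and 380 at an unadjusted p below 0.05 and 1 and 1 called by DESeq2.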

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

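The tests of the low-UMI cluster, the barcode sets, sex and the vehicle library with a tumour of its own for mitotic RNA were chosen only after the result was seen, as was the use of left-out libraries, a planned setting, to test 1 library in macrophages. The settings with sex as a term or 1 macrophage cluster were added after the data had been seen.

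LSN+PD-L1 27 stood far from the other libraries of its arms, farther than a test for single far values allows at the 95% level. Its type I interferon share of tumour-cell UMIs was 0.205% (nearest other LSN-treated library 0.118%) and its interferon gamma share 0.128% (0.0736%). Endothelial cells were 1.23% of its cells (nearest 7.24%). Macrophages and monocytes were 34.3%, against a nearest value of 7.10% among LSN-treated and 7.26% among PD-L1-treated libraries. In PD-L1 09, neutrophils were 3.43% of the cells (nearest 1.10%). The search covered 64 arms, and chance marks about 1 in 20.

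EGFP and Cas9, sequences added to the reference, had tumour-cell levels above both vehicle libraries in 4 libraries. EGFP reached 88.5 CPM in PD-L1 09, 113 in PD-L1 25, 84.6 in LSN 26 and 226 in LSN+PD-L1 12 (highest vehicle 54.7), from 1393, 1894, 1227 and 3540 UMIs. Cas9 reached 307, 406, 331 and 1022 CPM in those libraries (highest vehicle 250), from 4833, 6784, 4797 and 15980 UMIs. LSN 13 has no values for either.

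Mitotic RNA was higher in tumour cells of LSN-treated libraries. Without the low-UMI cluster (923 cells) the difference was 0.174 points, 83.8% of it (exact permutation p = 0.0317). That argues against those cells as the whole cause of the UMI share, where they weigh little. The mitotic-high difference fell more and leaves them open. Share differences were 0.0768 in the longer and 0.302 in the shorter barcode set and 0.201 among male and 0.229 among female libraries. Each was above the larger SD of its arms, which argues against sex as the whole cause. A batch stays open. In the longer set 0.0768 lay near the SD (0.0669), the mitotic-high difference was -1.08 points and the G2 and M phase median 0.010. Clusters made mostly of Vehicle 24 cells held 71.1% of its tumour cells, and the difference was 0.207 without them (exact permutation p = 0.0317) and 0.214 without that library (SD 0.114 and 0.103, p = 0.0714), which argues against a tumour of its own there as the whole cause. With the hemoglobin-rich one of these clusters alone out the difference was 0.170 (SD 0.116 and 0.124, exact permutation p = 0.0952), since the mean without LSN rose from 0.343% to 0.384%. An effect of the inhibitor and the histories of the animals stay open, and exact permutation p was above 0.05 without each single library but Vehicle 14 or LSN 26 (differences 0.168 to 0.224).

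Genes of 4 immune cell lists were higher in tumour cells of LSN-treated libraries. Free RNA of each library was scaled by 21 stroma and lung epithelium markers. For 30 members of these lists it predicted a median log2 difference of 0.692 (29 higher), against 0.846 observed (median difference 0.153, SD 0.501). It would give 98.7% of their level summed over libraries, but 53.3 of 136 CPM in PD-L1 25 and 881 of 621 in LSN+PD-L1 27. Free RNA may thus give most or all of these levels with LSN. It would be 1.61% to 5.29% of tumour-cell UMIs and 1.63% of the Aurka level, too little for the mitotic genes, and expression by tumour cells was not excluded.

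Interferon gamma response and MHC class I genes were higher in macrophages of PD-L1-treated libraries. A shift in the mix of macrophage clusters was first tested on shares (0.383 log2 with the mix held, 0.189 before; exact permutation p = 0.381 and 0.635), a test that cannot tell since the share had shown no difference to explain and rested on Vehicle 24 (without it 0.0745 and -0.0794); a second test, gene by gene, was then set. Within the 1 cluster with at least 20 cells in each library, 23 of 24 interferon gamma genes were higher with a median of 1.18 (camera adjusted p = 4.10e-10, estimated-correlation p = 0.0209), and with sex as a term 24 of 25 were, with a median of 1.22 (adjusted p = 1.07e-08, estimated-correlation p = 0.0634). Leaving out single libraries gave medians down to 0.336, without PD-L1 09, and p up to 0.00381 (adjusted) and 0.217 (estimated correlation), without Vehicle 24, where the median was 0.839 and 21 of 25 genes were higher. Values within the cluster argue against the mix as the whole cause of the list's rise, not as a part. Sex stays open, since only LSN-treated groups held both sexes. So do single libraries, chance (31 of 60 splits called as many lists) and PD-L1 blockade.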

How the results depend on the processing

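Tests with sex or barcode set as a term or subset, those that left out clusters, kept 1 macrophage cluster, joined macrophage classes or left out Vehicle 24 with LSN+PD-L1 27, and thinned CD8 shares were chosen only after the result was seen. The other settings here were planned. The rise of mitosis genes with LSN in tumour cells kept its direction and its camera call at the preset correlation in every setting run for lists, with medians from 0.26 to 0.93, and Aurka kept its direction with log2 fold changes from 0.83 to 1.29. Of the planned settings for counts, lists and measures, 355 stayed on their side of the threshold or within their spread, 69 moved, 5 reversed, 7 became weaker and 1 stronger. Of added ones 165 stayed, 37 moved, 6 reversed and 5 became weaker. For single genes and lists 3205 planned ones stayed, 87 reversed, 94 became stronger and 70 weaker, and 1424, 66, 3 and 68 of the added ones. Except where fewer libraries, cells or genes were tested, the cause was not tested. Tests planned for neutrophils and NK cells (under 20 cells in some libraries) and dendritic cells (no cluster found) were not run. No pairing was possible, as the groups share no replicate numbers. On simulated data with 200 genes changed, edgeR found 49% of 2-fold and 87% of 4-fold changes in tumour cells. T cells gave 60% and 91% and macrophages 31% and 91%. Many 2-fold changes would be missed, and real data may give less. Of unchanged genes edgeR called 8, 8 and 4, and DESeq2 34, 3 and 4.

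Counts are of genes called, gene values are log2 fold changes and list values their medians. Differences of treated from other libraries are in percentage points. Macrophages include monocytes. Values of genes and lists are from tumour cells where no others are named. With DESeq2 in place of edgeR, tumour cells gave 54 genes for the LSN effect, 10 for the PD-L1 effect, 6 for the interaction, 19 for LSN versus vehicle, 23 for PD-L1 versus vehicle, 7 for combination versus vehicle, 2 for combination versus LSN and 31 for combination versus PD-L1. T cells gave 3 genes for the PD-L1 effect. The LSN and PD-L1 effects had 2 and 4 genes in B cells, 12 and 32 in endothelial cells, 1 and 1 in fibroblasts and 20 and 6 in macrophages with DESeq2. With no filter on low counts, tumour cells gave 2 genes for the PD-L1 effect and 1 for PD-L1 versus vehicle. The LSN and PD-L1 effects had 63 and 102 genes in B cells, 52 and 80 in T cells, 148 and 322 in endothelial cells, 117 and 216 in fibroblasts and 55 and 53 in macrophages with no such filter. With the size factors of DESeq2 in edgeR, B cells gave 2 genes for the PD-L1 effect. With the compared groups alone in the fit, within tumour cells 1 gene was called for PD-L1 versus vehicle. With the mean over cells in place of the sum, LSN-treated libraries differed by 0.00351 in the interferon gamma gene share. With cells thinned to 1000 UMIs and at least 3 mitotic UMIs asked, LSN-treated libraries differed by 12.4 in the mitotic-high tumour cells. With immune cells as the whole, LSN-treated libraries differed by -0.918 in the share of NK cells, -5.74 in the share of alveolar macrophages and -3.43 in the share of macrophages. PD-L1-treated libraries differed by -4.12 in the share of alveolar macrophages and -2.38 in the share of macrophages.

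With sex as a term, tumour cells gave 1 gene for the PD-L1 effect and 1 for combination versus vehicle. Within T cells 1 gene was called for the PD-L1 effect. Macrophages gave 0 genes for the LSN effect and 0 for the PD-L1 effect. Camera called 0 lists for the PD-L1 effect in tumour cells. The G2 and M phase list had 0.038 and the mitosis list 0.041 for the PD-L1 effect. The mitosis list had -0.19 for the PD-L1 effect in macrophages. H2-D1 stood at -0.0036 for the LSN effect. Plk1 stood at 0.023, Mki67 at 0.11, Cxcl10 at -0.20, Rb1 at 0.14, Trp53 at -0.53, Rbl2 at 0.50, Hmmr at 0.048 and Ikzf2 at -0.98 for the PD-L1 effect. With the set of the barcode list as a term, within B cells 4 genes were called for the LSN effect and 3 for the PD-L1 effect. Rbl2 stood at 0.037 for the PD-L1 effect. With the 5 female libraries alone, B cells gave 9 genes for the LSN effect. Within macrophages 0 genes were called for the LSN effect. Camera called 3 lists for the LSN effect in T cells and 7 for the LSN effect in macrophages. The type I interferon response list had -0.23 for the LSN effect in macrophages. Aurkb stood at 0.31 and Isg15 at -0.61 for the LSN effect. Entpd1 stood at -0.042 for the LSN effect in T cells. LSN-treated libraries differed by 0.229 in the mitotic gene share, 0.00108 in the interferon gamma gene share, -2.02 in the share of alveolar macrophages, -0.0242 in the share of endothelial cells, -1.39 in the share of fibroblasts and -0.117 in the share of lung epithelium. With the 4 male libraries alone, macrophages gave 1 gene for the LSN effect. Camera called 8 lists for the LSN effect in macrophages. The MHC class I list had 0.0013 and the inflammatory macrophage list -0.36 for the LSN effect. Trp53 stood at -0.67 for the LSN effect. LSN-treated libraries differed by 0.201 in the mitotic gene share, -0.0523 in the share of NK cells, 0.285 in the share of neutrophils and -1.48 in the CD8 share of T cells. With the 5 libraries of shorter barcode lists alone, within B cells 0 genes were called for the LSN effect and 0 for the PD-L1 effect. Endothelial cells gave 12 genes for the PD-L1 effect. Within macrophages 0 genes were called for the PD-L1 effect. Camera called 0 lists for the LSN effect in macrophages. The type I interferon response list had -0.35 and the inflammatory macrophage list -0.21 for the LSN effect. The T cell exhaustion list had -0.015 for the LSN effect in T cells. Aurkb stood at 0.42, Ifit3 at -1.35 and Rb1 at 0.093 for the LSN effect. LSN-treated libraries differed by 0.302 in the mitotic gene share, -0.00134 in the interferon gene share and -0.133 in the share of NK cells. With the 4 libraries of longer barcode lists alone, B cells gave 4 genes for the LSN effect and 0 for the PD-L1 effect. Within T cells 3 genes were called for the PD-L1 effect. Macrophages gave 0 genes for the LSN effect and 0 for the PD-L1 effect. Camera called 4 lists for the PD-L1 effect in tumour cells, 4 for the LSN effect and 9 for the PD-L1 effect in macrophages. The interferon gamma response list had 0.23, the MHC class I list 0.16 and the dissociation and heat stress list 0.053 for the LSN effect. The S phase list had 0.036, the G2 and M phase list 0.14 and the mitosis list 0.18 for the PD-L1 effect. Mki67 stood at -0.39, Chga at 0.31, Cd274 at 0.015 and Rbl2 at -0.30 for the LSN effect. Ccnb1 stood at 0.053, Mki67 at 0.037, Chga at -0.43, Cd274 at -0.14, Rb1 at 0.022, Rbl2 at 0.96 and Depdc1a at 0.068 for the PD-L1 effect. LSN-treated libraries differed by 0.0768 in the mitotic gene share, 0.0245 in the interferon gamma gene share, -1.08 in the mitotic-high tumour cells, -1.61 in the share of alveolar macrophages, -0.860 in the share of fibroblasts, 0.294 in the share of neutrophils and -4.67 in the CD8 share of T cells. PD-L1-treated libraries differed by -1.25 in the share of endothelial cells and -0.0498 in the share of lung epithelium. With Vehicle 24 and LSN+PD-L1 27 both left out, within B cells 0 genes were called for the LSN effect. Macrophages gave 5 genes for the LSN effect. Camera called 3 lists for the PD-L1 effect in macrophages. The MHC class I list had 0.048 for the LSN effect. Aurkb stood at 0.080 and Ifit3 at -0.50 for the LSN effect. With the mitotic cluster of low UMI counts left out, the inflammatory macrophage list had -0.062 for combination versus vehicle. Aurka stood at -0.0057 for the PD-L1 effect. With the tumour cluster rich in hemoglobin RNA left out, H2-D1 stood at -0.0072 for the LSN effect. Aurka stood at -0.13 and Cxcl10 at -0.057 for the PD-L1 effect. LSN-treated libraries differed by 0.170 in the mitotic gene share. With alveolar macrophages included, within macrophages 0 genes were called for the LSN effect and 0 for the PD-L1 effect. Camera called 6 lists for the LSN effect and 8 for the PD-L1 effect in macrophages. The mitosis list had -0.40 for the PD-L1 effect in macrophages. Ccnb1 stood at -0.31 and Knstrn at -0.086 for the PD-L1 effect in macrophages. With the 1 macrophage cluster of at least 20 cells in each library alone, macrophages gave 0 genes for the LSN effect and 0 for the PD-L1 effect. Camera called 6 lists for the LSN effect in macrophages.

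Where a left-out library left 1 in its group, that lone sample was assumed to vary like the other groups. Counts with all libraries are followed by the lowest and highest without 1. For genes, the LSN effect had 0 (1 without PD-L1 25) in tumour cells, 1 (0 without Vehicle 14 and 8 without PD-L1 25) in B cells, 0 (1 without PD-L1 25) in T cells and 2 (0 without PD-L1 25 and 4 without PD-L1 09) in macrophages. For genes, the PD-L1 effect had 1 (0 without Vehicle 14 and 45 without PD-L1 25) in B cells, 0 (3 without LSN+PD-L1 12) in T cells, 0 (8 without LSN+PD-L1 12) in endothelial cells and 1 (0 without Vehicle 24 and 8 without PD-L1 25) in macrophages. For lists, the LSN effect had 8 (5 without Vehicle 14 and 10 without PD-L1 09) in tumour cells, 5 (3 without Vehicle 24 and 6 without LSN+PD-L1 12) in T cells and 1 (0 without Vehicle 24 and 4 without Vehicle 14) in macrophages. For lists, the PD-L1 effect had 7 (2 without Vehicle 14 and 9 without LSN+PD-L1 18) in tumour cells and 5 (3 without PD-L1 25 and 7 without PD-L1 09) in macrophages. For lists, combination versus vehicle had 10 (6 without Vehicle 14 and 12 without PD-L1 25) in tumour cells.

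Libraries left out are in parentheses. Further medians moved by over 1.5 times, with the call kept, follow. In tumour cells, for the LSN effect, G2 and M phase genes had 0.25 (LSN 13) and 0.32 (PD-L1 09). In tumour cells, for the PD-L1 effect, S phase genes had -0.33 (PD-L1 25) and -0.11 (LSN 13). MHC class I genes had 0.34 (PD-L1 25) and 0.36 (Vehicle 24). Regulatory T cell genes had 0.33 (LSN+PD-L1 18). In tumour cells, for combination versus vehicle, G2 and M phase genes had 0.17 (LSN+PD-L1 18). Interferon gamma response genes had 1.12 (Vehicle 24). Dissociation and heat stress genes had -0.64 (LSN+PD-L1 27). Tissue repair macrophage genes had 2.10 (Vehicle 14). In T cells, for the LSN effect, T cell exhaustion genes had 0.48 (PD-L1 09). S phase genes had 0.29 (LSN+PD-L1 27) and 0.40 (Vehicle 14). G2 and M phase genes had 0.16 (LSN+PD-L1 12) to 1.0 (PD-L1 25). In T cells, for the PD-L1 effect, T cell cytotoxicity genes had 0.33 (LSN+PD-L1 27). Regulatory T cell genes had 0.61 (Vehicle 14) and 0.62 (LSN 26). Type I interferon response genes had 0.19 (PD-L1 09). Interferon gamma response genes had 0.60 (PD-L1 25) and 0.60 (Vehicle 14). In macrophages, for the PD-L1 effect, mitosis genes had 0.29 (Vehicle 24) to 0.53 (LSN 26).

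Single libraries left out gave the S phase list -0.22 (PD-L1 09) to 0.0092 (PD-L1 25), the type I interferon response list -0.18 (LSN+PD-L1 27) to 0.48 (PD-L1 09), the interferon gamma response list -0.38 (LSN+PD-L1 27) to 0.53 (PD-L1 09), the MHC class I list -0.16 (Vehicle 14) to 0.15 (Vehicle 24), the inflammatory macrophage list -0.28 (LSN+PD-L1 27) to 0.58 (Vehicle 14) for the LSN effect. Single libraries left out gave the G2 and M phase list -0.40 (PD-L1 25) to 0.027 (PD-L1 09), the mitosis list -0.31 (PD-L1 25) to 0.056 (PD-L1 09), the type I interferon response list -0.14 (PD-L1 09) to 0.64 (Vehicle 24) for the PD-L1 effect. Single libraries left out gave the type I interferon response list -0.22 (LSN+PD-L1 27) to 1.08 (Vehicle 24), the MHC class I list -0.16 (Vehicle 14) to 0.44 (Vehicle 24), the inflammatory macrophage list -0.53 (LSN+PD-L1 27) to 2.57 (Vehicle 14) for combination versus vehicle. Aurkb ran from -0.37 to 0.39, Mki67 from -0.079 to 0.28, Chga from -0.68 to 0.036, H2-D1 from -0.13 to 0.18, Cd274 from -0.71 to 0.043, Isg15 from -0.14 to 0.50, Ifit3 from -0.58 to 0.75, Trp53 from -0.061 to 0.34, Rbl2 from -0.16 to 0.76 for the LSN effect. Aurka ran from -0.070 to 0.13, Plk1 from -0.41 to 0.0056, Mki67 from -0.33 to 0.028, Chga from -0.14 to 0.58, Cxcl10 from -0.13 to 0.40, Rb1 from -0.32 to 0.12, Trp53 from -0.13 to 0.27, Rbl2 from -0.38 to 0.53, Ikzf2 from -0.94 to 3.67 for the PD-L1 effect. Mitotic gene share differed by 0.168 (PD-L1 09) to 0.247 (LSN 26), the interferon gene share by -0.00140 (LSN+PD-L1 27) to 0.0332 (PD-L1 09), the interferon gamma gene share by -0.0183 (PD-L1 25) to 0.00825 (PD-L1 09), the share of NK cells by -0.0849 (LSN+PD-L1 18) to 0.151 (PD-L1 09), the share of alveolar macrophages by -0.888 (Vehicle 24) to 2.45 (PD-L1 25), by LSN treatment. The share of fibroblasts differed by -0.0912 (LSN 13) to 1.21 (LSN+PD-L1 27), the share of lung epithelium by -0.00802 (Vehicle 24) to 0.443 (PD-L1 09), the share of neutrophils by -0.790 (Vehicle 14) to 0.342 (PD-L1 09), the CD8 share of T cells by -1.60 (PD-L1 09) to 7.68 (Vehicle 24), by LSN treatment. Share of alveolar macrophages differed by -0.241 (PD-L1 25) to 2.29 (LSN 26), the share of endothelial cells by -0.467 (Vehicle 24) to 1.64 (LSN+PD-L1 27), the share of fibroblasts by -1.08 (Vehicle 14) to 0.529 (LSN 13), by PD-L1 treatment.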

Other observations

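Clusters of 1 library, hemoglobin and thinned CD8 shares were tests chosen only after the data had been seen; free RNA and the splits of the samples were not.

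Tumour cells of Vehicle 24 formed clusters of their own. In 3 tumour clusters 94.1%, 70.5% and 94.2% of the cells came from it, and Hba-a1, a hemoglobin gene, stood at 173 CPM in its tumour cells against 0 to 42.9 CPM in the other libraries. Free RNA would give 257% of the tumour-cell level of Wfdc17, but 1.55% of that of Plk1, 3.23% of H2-K1 and 3.03% of H2-D1. After thinning to 1000 UMIs, 31.0% to 50.7% of the T cells in a library had a Cd8a or Cd8b1 UMI.

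Treatment labels were moved among the libraries within each level of the other treatment, which gives 60 splits with the real one. For macrophage genes with LSN, 2 of the 60 splits, the real one included, gave as many genes (2; highest other 2). Taken alone this excludes chance, but as 1 of 18 unadjusted counts it does not, and no gene was called without PD-L1 25, LSN 13 or LSN 26 or with sex as a term. Chance cannot be excluded for the PD-L1 effect in macrophages (7 splits; real 1, highest other 3, from the split that follows sex), nor in B cells for LSN (6 splits; real 1, highest other 6) or PD-L1 (24; real 1, highest other 7). Where the real count was 0, all 60 splits gave as many, which was fixed in advance, so the splits cannot decide on chance. The highest others for LSN and PD-L1 were 1 and 7 in tumour cells and 13 and 12 in T cells. In endothelial cells they were 5 and 25 and in fibroblasts 5 and 6. The split that follows sex gave the 7 in tumour cells, 7 in T cells, 17 in endothelial cells and 3 each in fibroblasts and B cells. That of the shorter against the longer barcode set gave the highest counts in T cells (13 and 12), in B cells (6 and 7) and for LSN in tumour cells, and 1 for PD-L1 in macrophages, as many as the real one. With that set as a term, LSN and PD-L1 had 0 and 0 genes in T cells, 4 and 3 in B cells, 0 and 0 in tumour cells and 3 and 1 in macrophages. A split with all 4 longer lists in 1 arm gave 5 for LSN in fibroblasts and in endothelial cells. Splits that call several times the real count point to a structure of the samples.

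For gene lists chance cannot be excluded either. In tumour cells 10 splits gave as many lists as LSN (8; highest other 11) and 21 as many as PD-L1 (7; highest other 10). In T cells 12 splits gave as many as LSN (5; highest other 7) and 10 as many as PD-L1 (6; highest other 8). In macrophages all 60 gave as many as LSN (1; highest other 9) and 31 as many as PD-L1 (5; highest other 8).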
